A study of Drosophila melanogaster with 4 samples.

How the data were processed

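Adult Drosophila melanogaster were analysed in 4 libraries, 2 of RNA recovered with PABP on FLAG beads and 2 of total input RNA. Per the labels' protocols, ground flies were exposed to ultraviolet light, lysed and precipitated, RNA was extracted with Trizol, and libraries were made with the Ovation SoLo RNA-Seq kit. Per the submitters' processing notes, the tools were cutadapt 2.9, STAR 2.7.3a, SAMtools 1.10, Subread 2.0.0 with featureCounts, and DESeq2; their order and settings, the strand setting, the treatment of duplicate reads, and the genome build are not given in the sources used here. The deposited counts are whole-number read counts per gene, not normalized, for 17806 named genes, of which 4839 had 0 counts in all 4 libraries. A row with no gene name held at most 0.000418% of a library's counts and was left out. Per the file headers, a length in bases stands beside each gene; it equalled the whole gene span, introns included, for 17676 (99.6%) of the 17741 symbols matched to the RefSeq gene table of assembly Release 6 plus ISO1 MT (16984 directly, the rest through synonyms), so the counted features include introns. That table was used for names, lengths and gene overlaps only, and Dl and nos had no match in it. Because the authors' build is not given, no coordinates are printed. The names of 5 genes that had been turned into dates were settled by their length, dec-1 among them.

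The authors deposited a DESeq2 table that holds, per the file headers, log2 fold changes of IP over input with their standard errors, a Wald score, p-values and adjusted p-values, and a base mean. Its 4 library columns are a normalized signal, each equal to the deposited count divided by 1 size factor per library (3.22, 3.68, 1.09 and 1.51 for PABP IP 1, PABP IP 2, input 1 and input 2). It leaves 953 adjusted p-values as NA, which stayed NA, and 262 genes tested here are absent from it.

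Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM factors (0.760 and 0.728 for the IP, 1.33 and 1.36 for the input), glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes are the size of the fold change over the square root of the test's F. Where the input held few counts, these values can be smaller than the counting error alone. Input counts are therefore given for Sox21a, upd3, thw, Ets21C and Hsp70Bb. CPM values are counts scaled by the TMM library size. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the 23 lists. The test was run on simulated counts for the 9989 genes tested here, 200 of them changed, with the means and library sizes of the PABP IP and input comparison. On average 9676 simulated genes passed the filter, and changed genes that did not pass counted as missed. Over 5 runs the test recovered 47.2% of 1.5-fold, 72.8% of 2-fold, 92.4% of 4-fold and 96% of 8-fold changes with 4.4 false calls on average. Far more genes were called in the data (3708 higher and 3873 lower of 9989). The simulation, with few genes changed, therefore does not measure errors that come from the scaling of the libraries. Computations outside R used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

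Counts in the replicate libraries differed by more than sampling noise (chi-square per degree of freedom 7.93 over 10311 genes in the IP pair and 2.85 over 10073 genes in the input pair), so each library counted as 1 replicate. The common biological coefficient of variation was 7.98%. Total counts ranged from 2464629 to 10761349, so low values in the input are the least precise. Where a group had 1 to 3 counts, the ratio of summed counts scaled by TMM library size is given with an exact 95% interval. Against a group at 0 the fold is a bound from 3 counts over the group.

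Before the data were examined, the groups, the test, the 23 gene lists and the named genes were fixed. The rule named pAbp, 8 progenitor genes, 10 genes of other cell types, the 10 largest changes in each direction among genes past the adjusted p with a mean CPM of at least 10 in the higher group and both IP libraries on 1 side of both input libraries, and up to 4 members per list with the lowest p. Genes named as exceptions within a list, as its smallest changes, or as the rest of a called group of 5 or fewer were chosen after their values were seen, as were 6 further lists on signalling. Alternatives were RLE, upper-quartile, library-size and reduced-gene TMM scaling, 3 count filters, DESeq2 1.42.0, limma-voom, a replicate block, a test against a log2 fold change of 1, an adjusted p of 0.01, and each library left out in turn. The authors' size factors and a crossed block were added after the data were seen. Genes of overlapping position are uncertain: of the named genes 36 overlapped another gene in part, zfh2, ITP, pros, Snap25 and E2f1 among them, and 2 lay wholly inside another. For comparison with each list's median, 10000 random lists were drawn. In them each member was replaced by 1 of the 100 tested genes nearest in gene span and expression. Expression here was the sum of the mean IP and input CPM. That sum holds the IP level itself, so genes matched to a strongly risen member can be high in the IP as well. A list inside its matched range may therefore still differ from genes of equal input level.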

Results

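RNA carried by the poly(A)-binding protein (PABP), which coats the poly(A) tails of mRNAs, was profiled in adult Drosophila melanogaster by crosslinking and immunoprecipitation followed by sequencing (CLIP-seq). Whole flies, 200 per sample and 100 of each sex, were powdered and irradiated with ultraviolet light, which links proteins to the RNA they touch. The 2 PABP IP libraries hold RNA recovered with PABP on FLAG beads and are assigned by the labels to intestinal progenitor cells, the stem cells and enteroblasts that renew the gut lining. The 2 input libraries hold RNA of the total extract before precipitation and are assigned to all cells of the animal. Gene-level counts summed to 8987420 and 10761349 in PABP IP 1 and 2 and to 2464629 and 3346231 in input 1 and 2. Between 11670 and 12104 genes had at least 1 count per library. Mitochondrially encoded genes took 0.645% and 0.722% of the counts in PABP IP 1 and 2, against 5.90% and 4.59% in input 1 and 2. Log2 CPM correlated across genes at r = 0.993 between the IP libraries and r = 0.987 between the input libraries, and at r = 0.825 between the IP and input means; genes are not independent replicates. The labels do not say whether the 2 samples of a group came from separate collections of flies, so p-values measure only the spread between these samples, which may be technical.

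The comparison of IP with input asks which transcripts are carried by PABP of intestinal progenitors relative to the RNA of the whole animal. The series holds no control precipitation and no total RNA of progenitors alone. A fold change can therefore reflect expression in progenitors, binding by PABP or background on the beads. These cannot be told apart here. Genes that mark intestinal progenitors were far higher in the IP, and digestive enzymes, muscle, eye, fat body and germline genes were lower. The transcript of pAbp itself, the gene of the precipitated protein, was 10.1-fold higher, at a TMM-normalised CPM of 13274 ± 204 in the IP and 1310 ± 108 in the input (SD, n = 2 each; log2 fold change 3.34 ± 0.18 SE, adjusted p = 2.59e-11). Counts of the endogenous gene and of any tagged copy are not separated in these values. Of 9989 genes tested, 3708 were higher and 3873 lower in the IP (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), so that 48.9% of the calls were higher. This split moved with the scaling of the libraries: 31.0% of the calls were higher with upper-quartile factors (2574 higher, 5719 lower), 25.8% with library size alone (2209 higher, 6347 lower) and 33.8% with the authors' size factors (2750 higher, 5384 lower). The median log2 fold change of all tested genes was -0.10 in the main scaling and -0.71, -0.95 and -0.59 under these 3, so each change here is relative to a zero point set by TMM.

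All 21 progenitor genes tested were higher in the IP, with a median log2 fold change of 3.80. The transcription factor gene Sox21a, which acts in progenitor differentiation, showed the largest change of all named genes, from 1.12 ± 0.289 CPM in the input to 995 ± 34.3 CPM in the IP (SD, n = 2 each; log2 fold change 9.73 ± 0.22 SE, adjusted p = 8.55e-15). Input 1 and 2 held only 3 and 6 counts of Sox21a, so this SE understates the error. The snail-family repressor gene esg, the standard progenitor marker, rose 273-fold (log2 8.09 ± 0.19 SE, adjusted p = 8.55e-15), and Dl, the Notch ligand that marks the stem cells, rose 40.2-fold (log2 5.33 ± 0.16 SE, adjusted p = 3.78e-14). The transcription factor genes Sox100B and zfh2 had log2 fold changes of 8.21 and 6.73. Genes of the receiving side of Notch signalling rose as well: the enteroblast factor klu by 4.94, E(spl)m3-HLH by 7.48, E(spl)malpha-BFM by 7.55 and E(spl)mbeta-HLH by 2.97 on the log2 scale, while the receptor gene N, used in many tissues, rose by 1.36 ± 0.11 (SE, adjusted p = 3.36e-09). The smallest rises were those of Piezo (0.36) and Pvr (0.48), both of which fell with library size alone, where 18 of the 21 genes were higher and 2 lower, and Piezo was not called without input 2 (0.27). The list stood above the other genes in camera with its preset correlation (adjusted p = 4.16e-20) but not with an estimated correlation (adjusted p = 0.338). Its median exceeded those of all 10000 random lists matched on gene length and expression, whose median was 0.93. The progenitor gene spdo, a Notch pathway component, had 0 counts in all 4 libraries and lies wholly inside PH4alphaEFB, as mira lies inside Hs6st. Of the 1933 protein-coding genes lying wholly inside another gene, 99.4% had 0 counts in all 4 libraries, so an absence of spdo or mira RNA cannot be read from these counts.

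**Figure D1:**
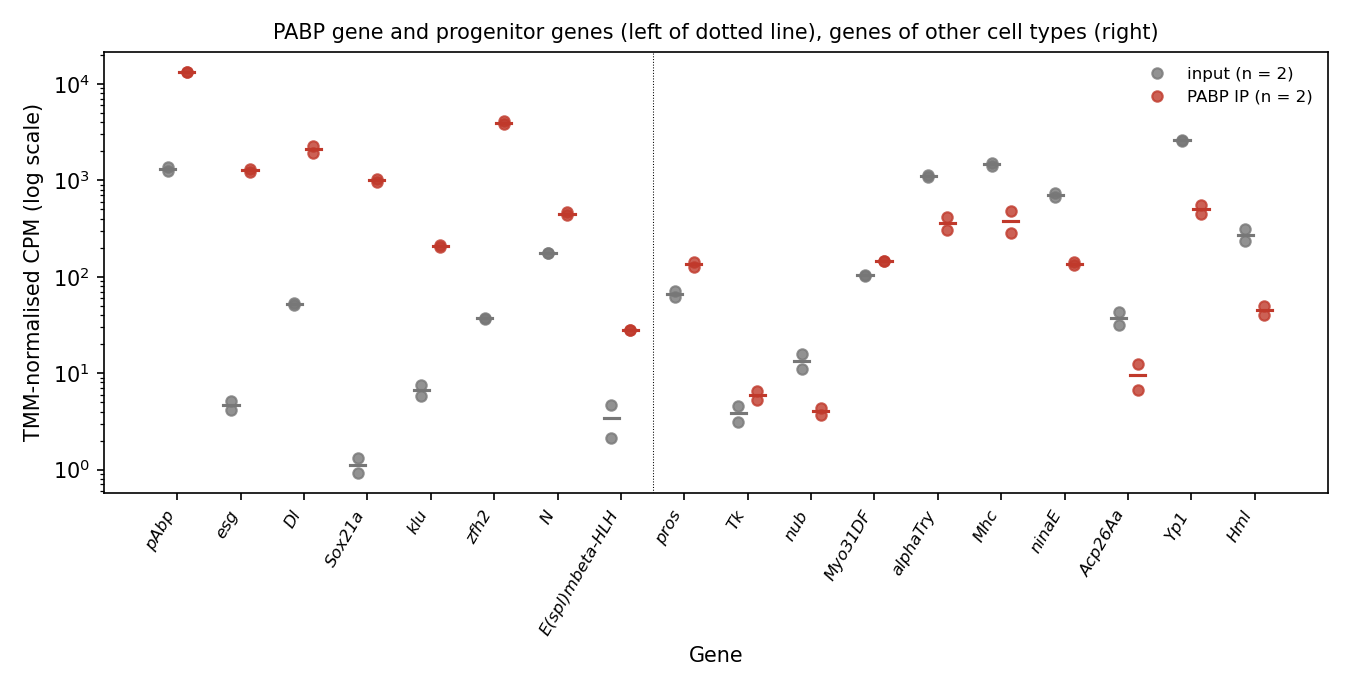
TMM-normalised CPM on a log axis for pAbp and 7 progenitor genes (left of the dotted line) and 10 genes of other cell types (right), with 1 point per library and a bar at the mean of the 2 libraries of each group, input in grey and PABP IP in red. Both IP libraries lie above both input libraries for pAbp and each progenitor gene shown, while Yp1, Mhc, ninaE and Hml lie lower in the IP; Myo31DF, slightly higher here, has a negative fold change under upper-quartile, library-size and authors' scaling.

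Among genes with a mean CPM of at least 10 in the IP, the 10 largest rises also included upd3, upd2, sty, thw, CG43187 and lncRNA:CR45658. The cytokine gene upd3, a ligand gene of the JAK/STAT pathway, had 1.31 ± 0.299 CPM in the input and 551 ± 35.2 CPM in the IP (SD, n = 2 each; log2 fold change 8.72 ± 0.20 SE). Its counts in input 1 and 2 were 5 and 5, so this SE understates the error. Only 1 input count was recorded for upd2, a second ligand gene of this pathway, which gives an IP to input ratio of 217 with a 95% counting interval of 38.8 to 8603. The receptor tyrosine kinase antagonist gene sty had a log2 fold change of 7.67 ± 0.21 SE (adjusted p = 1.65e-14), and thw one of 8.10 ± 0.21 SE. For thw, input 1 and 2 held 2 and 7 counts, so its SE is too small as well. The uncharacterised gene CG43187 had 2 input counts and a ratio of 602 (166 to 4974). No input count was recorded for lncRNA:CR45658, which was at least 27.2-fold higher in the IP against a floor of 3 counts over the input group. These intervals and floors cover counting error only.

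Enterocytes, the absorptive cells that progenitors produce, showed the opposite direction. Of 23 enterocyte markers and digestive enzymes, 21 were lower and 2 higher, with a median log2 fold change of -2.40. Amylase genes Amy-p and Amy-d, near-identical copies whose reads cannot be cleanly divided, changed by -3.06 and -3.23, the maltase gene Mal-A1 by -2.99 and the trypsin gene thetaTry by -2.90 on the log2 scale. The enterocyte transcription factor gene nub fell from 13.5 ± 3.42 to 4.05 ± 0.488 CPM (SD, n = 2 each; log2 -1.71 ± 0.28 SE, adjusted p = 3.59e-05), and alphaTry changed by -1.60 ± 0.14 SE. The 2 genes that rose were lab, the homeobox gene of copper cells, at 2.61 ± 0.39 SE, and Myo31DF, a myosin of the enterocyte brush border, at 0.48 ± 0.10 SE (adjusted p = 0.000348). Myo31DF changed sign under other scalings, to -0.13 with upper-quartile factors, -0.37 with library size alone and -0.0166 with the authors' factors. The list lay below the other genes in camera (adjusted p = 9.42e-11), a call not kept with an estimated correlation (adjusted p = 0.376).

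Enteroendocrine markers, genes of the hormone-secreting gut cells, moved both ways. The input holds RNA of all tissues, so these changes do not give their levels in enteroendocrine cells. Of 14 tested, 4 were higher and 4 lower, and the list did not differ from the other genes (camera adjusted p = 0.986; 0.992 with an estimated correlation); its median was -0.06 and its mean 0.19. With library size alone 2 were higher and 7 lower (median -0.91), and with upper-quartile or the authors' factors 3 were higher and 5 lower. The peptide gene ITP rose from 8.36 ± 0.267 to 207 ± 46.8 CPM (SD, n = 2 each; log2 4.64 ± 0.19 SE, adjusted p = 8.31e-13). The transcription factor genes Ptx1 and pros rose by 1.37 and 1.01, and the peptide gene CCHa1 by 1.07 (adjusted p = 0.0431), a call lost without input 1 (1.06) or input 2 (1.07), with upper-quartile factors (0.47), library size alone (0.22) or the authors' factors (0.58), in DESeq2 (1.15) and in limma-voom (0.96). The rise of pros was not called with library size alone (0.16), and the authors' deposited table gives it a log2 fold change of 0.51 with an adjusted p of 0.109. The peptide-processing genes amon and 7B2 changed by -1.61 and -1.50, and the peptide genes CCHa2 and Mip by -0.91 and -1.97, with CCHa2 not called without input 2 (-0.60) and Mip not called in DESeq2 (-1.98). For the tachykinin gene Tk the difference did not pass the threshold (0.66 ± 0.34 SE, adjusted p = 0.0858).

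Genes of most tissues outside the gut lining were lower in the IP. All 15 muscle genes fell (median -1.95, camera adjusted p = 1.69e-09; adjusted p = 0.338 with an estimated correlation), including the myosin heavy chain gene Mhc at -1.95 ± 0.18 SE and the muscle actin gene Act79B at -3.10 ± 0.15 SE. Among 15 photoreceptor genes 13 fell (median -2.25, adjusted p = 8.36e-08; adjusted p = 0.338 with an estimated correlation), among them the rhodopsin gene ninaE (-2.36), Arr1 (-3.00) and trp (-2.66); norpA (-0.05) and inaE (0.09) were not called in the main scaling. All 12 fat body and yolk protein genes fell (median -2.33, adjusted p = 6.58e-07; adjusted p = 0.354 with an estimated correlation), with Yp1 at -2.37, Yp2 at -2.68, the lipid carrier gene Apoltp at -2.64 and the storage protein gene Lsp2 at -3.58. Of 10 hemocyte and basement membrane genes 8 fell, such as Hml (-2.61) and the collagen gene Col4a1 (-1.91), and crq (0.75) and srp (0.32) rose, though neither was higher with library size alone and srp lost its call without PABP IP 1 (0.33), PABP IP 2 (0.32) or input 2 (0.20) and in DESeq2 (0.39) (median -1.87, adjusted p = 0.00099; adjusted p = 0.414 with an estimated correlation). All 6 Malpighian tubule genes fell, with Alp4 at -1.83 (median -1.27, adjusted p = 0.0268; adjusted p = 0.489 with an estimated correlation), and their median lay just inside the 95% range of matched random lists (-1.28 to 0.89).

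Neuronal and glial genes were mixed. Of 13 neuronal genes 5 fell, including the vesicular glutamate transporter gene VGlut (-2.34 ± 0.21 SE) and Gad1 (-1.26), 7 were not called and the synaptic fusion gene Snap25 rose (1.78 ± 0.14 SE, adjusted p = 2.92e-09). The neuronal list did not differ from the other genes (median -0.21, camera adjusted p = 0.209; adjusted p = 0.658 with an estimated correlation). With library size alone 11 of the 13 were lower. Of 6 glial genes Eaat1 (-2.01), repo (-1.67) and Gs2 (-1.31) fell and nrv2 rose (0.98), a rise not called with library size alone, and the list did not pass (median -0.53, adjusted p = 0.232; adjusted p = 0.421 with an estimated correlation).

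Reproductive genes of both sexes were lower. In the female germline list 16 of 18 fell (median -1.97, camera adjusted p = 4.03e-09; adjusted p = 0.338 with an estimated correlation). The posterior determinant nos had the lowest fold change of all named genes, from 46.9 ± 6.13 CPM in the input to 2.49 ± 0.627 CPM in the IP (SD, n = 2 each; log2 -4.20 ± 0.23 SE, adjusted p = 2.49e-11), and osk and orb changed by -2.44 and -2.28. Its 2 exceptions were grk (1.15) and BicD (0.79), neither of which was higher with library size alone. All 11 eggshell genes fell, with dec-1 at -2.91 and Vm26Aa at -1.85 (median -1.65, adjusted p = 3.54e-05; adjusted p = 0.414 with an estimated correlation). Of 21 testis genes 15 fell, such as the germline tubulin betaTub85D (-2.06) and S-Lap1 (-1.74), and the spermatocyte transcription gene mia rose (1.8 ± 0.18 SE) (median -1.23, adjusted p = 0.00275; adjusted p = 0.40 with an estimated correlation). All 10 male accessory gland genes fell, with the seminal fluid protein genes Acp26Aa at -1.92 and SP at -2.28 (median -1.84, adjusted p = 0.000463; adjusted p = 0.376 with an estimated correlation).

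**Figure D2:**
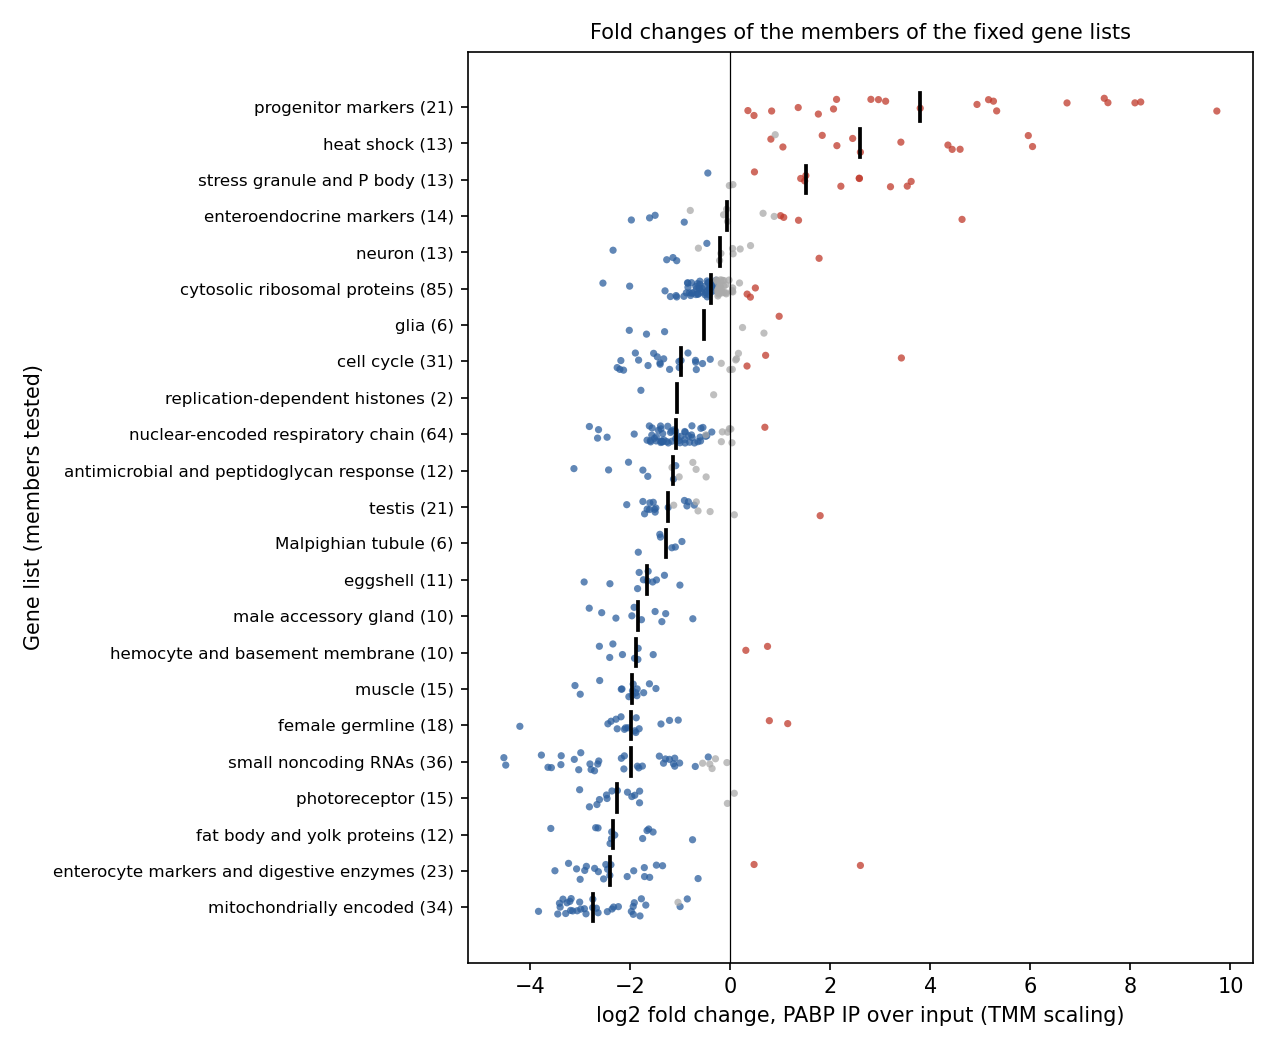
Log2 fold change of PABP IP over input in the TMM scaling (x axis) for each tested member of the 23 fixed gene lists (rows, with the number tested), drawn red where higher, blue where lower and grey where not called at an adjusted p of 0.05, with a black bar at the list's median; vertical offsets within a row carry no meaning. Progenitor (3.80), heat shock (2.61) and stress granule (1.52) genes have the highest medians and mitochondrially encoded genes (-2.74) the lowest; ribosomal protein genes lie near 0 here and at a median of -1.23 with library size alone.

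Heat shock genes were higher in the IP, with 12 of 13 called and a median of 2.61 (camera adjusted p = 3.58e-07; adjusted p = 0.338 with an estimated correlation). The small chaperone gene Hsp23 rose from 19.4 ± 0.668 to 1212 ± 43.6 CPM (SD, n = 2 each; log2 5.96 ± 0.15 SE, adjusted p = 1.25e-14). Hsp68 rose by 4.44 ± 0.13 SE, the co-chaperone gene stv by 2.45 ± 0.11 SE and the abundant chaperone gene Hsp83 by 2.61 ± 0.18 SE. The 4 tested copies of Hsp70, near-identical in sequence and so uncertain one by one, were all higher, Hsp70Bb by 6.04 ± 0.32 SE and Hsp70Bc with a ratio of 22.4 (95% counting interval 6.0 to 188) from 2 input counts. For Hsp70Bb, input 1 and 2 held 6 counts and 1 count, so its SE understates the error. With library size alone 10 of the 13 were higher and none lower. Of 13 genes encoding proteins of stress granules and P bodies, cytoplasmic assemblies of untranslated mRNA, 10 were higher and 1, the decapping gene DCP1 (-0.44; not called without input 2, -0.16, or in DESeq2, -0.36), lower (median 1.52, adjusted p = 3.54e-05; adjusted p = 0.372 with an estimated correlation). DCP2 rose by 3.62, rin by 3.54, Edc3 by 3.21 and Fmr1 by 2.59 on the log2 scale. This median lay at the 27.5th percentile of random lists matched on gene length and expression, whose own median was 1.81. The matching uses the IP level too, which can raise the matched median. With library size alone 9 of these 13 genes were higher and 4 lower.

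Cell cycle genes were mostly lower, with 22 of 31 called lower, 3 higher and a median of -0.98 (camera adjusted p = 0.000127; adjusted p = 0.354 with an estimated correlation). The replication helicase genes Mcm2, Mcm3 and Mcm5 changed by -2.25, -2.20 and -2.13. The S-phase transcription factor gene E2f1 rose from 116 ± 2.76 to 1243 ± 132 CPM (SD, n = 2 each; log2 3.42 ± 0.13 SE), and the mitotic phosphatase gene stg (0.71) and the midzone gene feo (0.34; not called without input 1, 0.20) rose less. Only 1 of the 31 was higher with library size alone or with the authors' factors. Most female germline genes, which come from a tissue rich in dividing cells, fell alongside, as given in the germline list. Whether these falls are linked was not tested. Antimicrobial and peptidoglycan-response genes were lower in 7 of 12 cases, including PGRP-SC2 (-2.03), PGRP-SC1a (-2.43), AttC (-1.74) and Drs (-1.08), and 5 were not called. With upper-quartile factors, library size alone or the authors' factors all 12 were lower. Their list call, a comparison with the other genes (median -1.14, adjusted p = 0.0396), was lost with an estimated correlation (adjusted p = 0.394), with upper-quartile factors (adjusted p = 0.131), with library size alone (0.173), with the authors' factors (0.105), in DESeq2 (0.0555) and without PABP IP 2 (0.0577). The list's median lay at the 17.2nd percentile of random lists matched on gene length and expression, whose own median was -0.83 (95% range -1.45 to 0.04).

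Mitochondrially encoded genes were lower in the IP, as were most of the few small noncoding RNAs that could be tested. Of 34 mitochondrially encoded genes 33 fell (median -2.74, camera adjusted p = 5.94e-11; adjusted p = 0.393 with an estimated correlation). The respiratory complex gene mt:ND3 fell from 367 ± 40.7 to 34.9 ± 1.16 CPM (SD, n = 2 each; log2 -3.39 ± 0.12 SE), and mt:ATPase8 changed least among those called (-0.85). Of 36 small noncoding RNAs tested 31 fell and 5 were not called (median -1.98, adjusted p = 8.79e-06; adjusted p = 0.421 with an estimated correlation), with the signal recognition particle RNA 7SLRNA:CR32864 at -3.37 ± 0.20 SE and snRNA:7SK at -1.82 ± 0.15 SE. The other 601 of the 637 on this list did not pass the count filter, so the class as a whole cannot be judged. The nuclear genes of the respiratory chain also fell in 56 of 64 cases, with ND-51 at -1.91 and COX5A at -1.51, and COX7A rose (0.70), though no member was higher with library size alone (median -1.09, adjusted p = 5.21e-09; adjusted p = 0.414 with an estimated correlation). Of the 2 replication-dependent histone genes tested, His2B:CG33868 fell (-1.78) and His1:CG33801 was not called (-0.33 ± 0.50 SE), and the list did not pass (median -1.05, adjusted p = 0.236; adjusted p = 0.421 with an estimated correlation). The other 109 of its 111 members did not pass the count filter. Among 85 cytosolic ribosomal protein genes 51 were lower, RpS27 (0.51), RpL35 (0.41) and RpL37a (0.34) were higher and 31 were not called (median -0.38, adjusted p = 0.000524; adjusted p = 0.626 with an estimated correlation). The list's median lay at the 11.5th percentile of matched random lists, inside their 95% range of -0.59 to 0.39. None of the 85 was higher and all were lower with library size alone, and 82 were lower with the authors' factors. RpL35 was not called without input 1 (0.33), nor was RpL37a without PABP IP 1 (0.24) or input 1 (0.24). RpLP0 changed by -1.19 and RpS5b, a paralogue used in the germline, by -2.00.

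Adjusted over the list alone, the counts of higher and lower members equalled those adjusted over all genes in every list except the enteroendocrine one (3 higher, 4 lower) and the ribosomal one (3 higher, 50 lower). No list passed with an estimated correlation, a test that rests on 2 residual degrees of freedom.

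The authors' deposited table gives the same contrast for 12247 genes, of which it calls 2404 higher and 4349 lower at an adjusted p below 0.05. Its base means show that its fit also held libraries not analysed here. Its standard errors and adjusted p-values thus rest on another set of samples. Of the 9727 genes present there and tested here, 2394 were higher in both and 3414 lower in both. Only CG3356, Sec31, pic and Synd, chosen after their values were seen, were called in opposite directions, higher here and lower in the authors' deposited table. All 4 lost their call without input 1 (0.24, 0.24, 0.26 and 0.30), as did Sec31 and pic without PABP IP 1 (0.25 and 0.21), Synd without PABP IP 2 (0.19) and Sec31, pic and Synd without input 2 (0.27, 0.23 and 0.18). The log2 fold changes of the 2 tables differed by a median of 0.50, this fit being higher, and correlated at r = 0.9999 across genes. With the authors' size factors the median log2 fold change of all genes tested here was -0.59, against -0.10 in the main scaling. CG3356, Sec31, pic and Synd then had log2 fold changes of -0.20, -0.24, -0.24 and -0.25. The offset and the opposite signs thus follow the scaling of the libraries. For pAbp the authors' deposited table gives 2.84, and for esg 7.59. Of the genes named by the fixed rule and present in both, 5 called here are not called there: Yp1 (-2.87 ± 1.36 SE, adjusted p = 0.0582), Lsp1beta (-2.81, adjusted p = 0.0704), Irk3 (-1.65, adjusted p = 0.0712), pros (0.51) and Myo31DF (-0.0164, adjusted p = 0.985). Of the other genes named, Piezo, Pvr, CCHa1, srp, grk, BicD, stg, feo, COX7A, RpS27, RpL35 and RpL37a are called higher here and not called there, and norpA (-0.55, adjusted p = 0.0378) is called lower only there.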

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

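A signal outside the main measurement was seen in the authors' deposited table. It gives a base mean above 0 for 959 genes that have 0 counts in all 4 libraries. A base mean averages normalised counts over the libraries of a fit, so these genes had counts in libraries not analysed here. The base mean lay within 1% of the mean of the 4 library columns for only 146 of 12247 genes, and the median ratio of the 2 was 1.43. The geometric mean of the 4 size factors was 2.10. No technical or biological explanation of the counts of these 959 genes was tested.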

How the results depend on the processing

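The authors' size factors and the crossed block were chosen after seeing the data. Higher and lower counts stayed within 1.5 times of 3708 and 3873 except with library size alone (2209 higher, 6347 lower), where the scaling lowers all fold changes by about the same amount, and in the test against a log2 fold change of 1 (2145 higher, 1584 lower), which asks for a larger change. Leaving out each library gave 3458 to 3645 higher and 3218 to 3599 lower, the lone library being assumed to vary like the other group. DESeq2 called 3507 higher and 2769 lower. Progenitor and enterocyte lists kept their direction in each alternative and their call in all but camera with an estimated correlation (medians 3.80 and -2.40, adjusted p = 0.338 and 0.376); the 2 residual degrees of freedom limit that test. Of the genes named by the fixed rule only Myo31DF reversed, to a log2 fold change of -0.13 with upper-quartile factors, -0.37 with library size alone and -0.0166 with the authors' factors; the cause is the lower zero point of these scalings. Of 44 genes named beyond that rule, chosen after seeing the data, these turned sign under the same 3 scalings, in that order: Piezo (-0.25, -0.49, -0.14), Pvr (-0.13, -0.37, -0.018), inaE (-0.52, -0.77, -0.41), srp (-0.29, -0.54, -0.18), feo (-0.27, -0.51, -0.16), RpL35 (-0.20, -0.44, -0.091), RpL37a (-0.27, -0.51, -0.16), CG3356 (-0.31, -0.55, -0.20), Sec31 (-0.35, -0.59, -0.24), pic (-0.36, -0.60, -0.24), Synd (-0.36, -0.61, -0.25) and Thor (-0.52, -0.76, -0.40). RpS27 did so with upper-quartile factors (-0.10) and library size alone (-0.35), and crq (-0.10), BicD (-0.067), stg (-0.14) and COX7A (-0.16) with library size alone. Under the same 3 scalings norpA, chinmo and Notum were called lower. None of the 44 turned sign in DESeq2, where 6 lost their call, with a filter of 5 CPM in 2 libraries, where 7 did, or without 1 library, where 3 to 9 did. Of the genes of the rule, pros (0.16) and nrv2 (0.13) lost their call with library size alone. His1:CG33801 gained one there and without PABP IP 1 (-1.17 and -1.44). The fry test asks whether a list moves 1 way against no change, not against other genes: the ribosomal list did not pass it (adjusted p = 0.0782), and the glial (0.0171) and histone (0.0256) lists did. The antimicrobial list also lost its call in the crossed block (adjusted p = 0.0638). The labels do not say that equal replicate numbers pair libraries, and deviations of same-numbered libraries correlated at -0.19 across genes; with a replicate block 3660 genes were higher and 3817 lower, of which 3644 and 3783 were also called without it, and no gene named by the rule and no list changed its call, while srp (0.32), RpL37a (0.34), Sec31 (0.26), pic (0.25) and Synd (0.25) lost theirs. A crossed block gave 3822 higher and 4032 lower. Input depth limits genes near 1 CPM, and 1.5-fold changes were recovered in 47.2% of simulated cases, in simulations with few genes changed.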

Other observations

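The signalling lists in this part, the carry-over test and the heat shock test were chosen only after the results were seen. Since the signalling lists were drawn up with values in view and some hold genes already named among the largest rises, no test p-value is given for them, and the medians and comparisons with matched random lists only describe them. All 11 genes of the JNK and AP-1 response rose (median log2 fold change 3.52, above all 10000 random lists matched on gene length and expression, 95% range 0.03 to 2.30), led by the ETS factor gene Ets21C (7.23 ± 0.18 SE) and Atf3 (6.04 ± 0.17 SE), with the JNK phosphatase gene puc at 4.52, the Fos gene kay at 3.65 and the matrix protease gene Mmp1 at 3.45. For Ets21C, input 1 and 2 held 8 and 9 counts, so its SE understates the error. All 8 EGFR ligand and feedback genes rose (median 3.52, matched range 0.30 to 2.69), among them sty (7.67), the ligand genes vn (4.71) and spi (2.85) and the ERK phosphatase gene Mkp3 (4.29). Without sty, one of the largest rises, the median of the 7 others was 3.45 (matched range -0.095 to 2.66). All 5 E(spl) genes rose (median 4.29), 4 of which also belong to the progenitor list, so this is not separate evidence.

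The medians of the 3 other lists lay inside their matched ranges. Since the matching uses the IP level too, this does not settle whether they differ from genes of equal input level. Among 9 JAK/STAT genes 6 rose, including upd3 (8.72) and the feedback gene Socs36E (5.08), zfh1 (-1.02) and et (-1.14; not called without input 2, -0.74, or in DESeq2, -1.05) fell and chinmo was not called, though it was lower with upper-quartile factors (-0.87), library size alone (-1.11) and the authors' factors (-0.75). Their median of 1.19 lay inside the matched range (-0.71 to 1.91), and without upd3 and upd2, already among the largest rises, and dome and Stat92E, also on the progenitor list, the median of the 5 others was -0.26. Of 9 insulin and TOR genes 8 rose, InR by 4.05 ± 0.16 SE, and Thor was not called (0.10), with a median of 1.94 (matched range -0.17 to 2.12). With upper-quartile factors, library size alone or the authors' factors 6 of these 9 were higher and 2 lower, and 7 were higher in DESeq2 and without any 1 of the libraries. Of 5 Wnt targets 3 were higher (median 1.51, matched range -1.21 to 1.99). The target fz3 was lower (-0.55), a call lost without PABP IP 2 (-0.51) or input 1 (-0.29), with RLE factors (-0.48), with no filter (-0.48) and in DESeq2 (-0.49), and Notum was not called, though it was lower with upper-quartile factors (-1.17), library size alone (-1.41) and the authors' factors (-1.06). Across all tested genes, longer genes were higher in the IP (Spearman rho 0.28 between gene span and log2 fold change, genes not being independent replicates), with a median span of 4139 bases in higher and 2144 bases in lower genes.

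Genes of other tissues were lower in the IP by unequal amounts, and each list kept part of its input level: their summed share of all library counts (no TMM factor) in the IP was 14.4% of that in the input for muscle, 16.1% for photoreceptor, 10.4% for fat body, 17.2% for eggshell, 15.8% for accessory gland, 24.1% for hemocyte and 17.0% for female germline genes. A uniform carry-over of whole-animal RNA, if nothing else acted, would give 1 fold change for all of them. Over the 57 genes of the first 6 of these lists with an input CPM of at least 20, female germline genes left out, the SD of log2 fold changes (0.80) was 5.95 times their median standard error (0.13), and over the 53 of them called lower, a selection that narrows the spread, the SD (0.54) was 3.91 times theirs. These values are the unequal falls themselves, which a uniform carry-over acting alone forbids, so they argue against that alone and say nothing of other causes. A uniform carry-over together with expression of some of these genes in progenitors stays open. A strong link with gene span, introns included, is argued against for these genes, with a Spearman rho of -0.033 over the 57 genes (permutation p = 0.806, 95% bootstrap interval -0.32 to 0.25). A weaker link in either direction stays open. Transcript length was not tested and stays open. A carry-over that differs between transcripts, for example by poly(A) tail, and low expression of some of these genes in progenitors may both contribute and were not tested.

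Heat shock genes were higher in the IP, which sequences derived from hsp70 in a transgene could in principle produce for the Hsp70 copies. The 9 other members argue against this as the whole cause of the list's rise: 8 of them were higher and their median log2 fold change was 2.14, while the 4 Hsp70 copies had a median of 4.48. They cannot show whether such sequences added to the Hsp70 copies, so that stays open. Expression in progenitors, a response of these cells to handling, and a preference of PABP for these mRNAs stay open and were not tested.

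The 0 counts of spdo and mira may come from their position. Of 1933 protein-coding genes lying wholly inside another gene, 99.4% (95% Wilson interval 98.9 to 99.6) had 0 counts in all 4 libraries, against 3.87% of the 11833 others. The same held for 47 of the 70 list members that were not tested outside the noncoding and histone lists, such as the enterocyte genes Ssk and Tsp2A. Whether progenitors carry spdo or mira RNA cannot be read from these counts.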
